A study of Homo sapiens with 48 samples.

How the data were processed

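Small RNA sequencing was done on 8 human breast cancer cell lines that carried a doxycycline-inducible dCas9-KRAB protein, a catalytically dead Cas9 fused to a transcriptional repressor domain (CRISPR interference). Per the labels' protocols, cells received lentivirus with an sgRNA and were kept in 1 ug/mL doxycycline for 7 passages. The labels of the 24 CTRL libraries give the treatment as untreated, which differs from that protocol, so the sgRNA in the label was used to form the groups. Total RNA was isolated with the miRNeasy kit, and 1000 ng went into TruSeq small RNA libraries. Each line had 3 libraries with a negative control sgRNA (CTRL 1 to 3) and 3 with an sgRNA against ZSWIM8 (KD 1 to 3), 48 libraries in all. The number of a library is the number of its sgRNA, so the 3 libraries of a group carried different guides. The numbers recur in all 8 lines, while the tests take the libraries as independent. Nothing in the labels says that they came from separate cultures, and p-values measure the spread between these libraries only, which may be partly technical.

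The deposited table lists 1806 mature miRNAs in 48 library columns, all of them used. The values are counts-per-million (CPM) made by the authors and rounded to 1 decimal, although the table calls them TPM: most columns sum to 1000000, and low values in a column are multiples of 1 constant step, with no scaling by length. Adapter trimming with cutadapt 1.9.1 and alignment with Bowtie are named per the submitters' processing notes. The Bowtie version, genome build, miRNA annotation, counting rule and filters are not given in the sources used here. Blank cells fall in 4 patterns, so the table seems to have been joined from 4 tables. SUM159PT has 1505 miRNAs listed and 301 blank. BT-549, MDA-MB-231 and MDA-MB-436 share 1521 listed and 285 blank. MCF-7 and MDA-MB-361 share 1467 listed and 339 blank, and T47D and SK-BR-3 share 1120 listed and 686 blank. A total of 966 miRNAs are listed for every line. The listed values cover 77.7% to 78.9% of the CPM total in T47D and 62.7% to 64.2% in SK-BR-3, so levels in these lines are relative to a total that is listed here only in part. Columns that spell the line BT459 were taken as BT-549.

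The CPM worth of 1 read was estimated per library from the spacing of values up to 20 CPM, which gave depths of 1.80 M to 6.02 M reads (median 3.06 M). From 87.5% to 100.0% of these low values lay within 0.05 CPM of a whole multiple. Whole reads could not be recovered for nearly all miRNAs, because rounding to 1 decimal blurs the step, so no count model was run. No 2 columns shared more than 9.58% of their nonzero values. In 48 pairs of replicates, squared differences of miRNAs of at least 100 CPM averaged 12.8 to 472 times the counting variance. No pair therefore looked like 1 library deposited again. On average over these abundant miRNAs, counting error was a small part of the spread. Its part was not measured for miRNAs under 100 CPM, so nothing is concluded for them.

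Tests were run on log2(CPM + 1) with limma 3.58.1 in R 4.3.3, with a mean-variance trend and two-sided moderated tests. P-values were adjusted by the Benjamini-Hochberg method, and a miRNA was called at an adjusted p under 0.05. A log2 change on this scale understates the change of miRNAs with low values. The all-line comparison took the mean of the 8 within-line differences over the 48 libraries. It used miRNAs listed for all lines with at least 10 CPM in at least 3 libraries. The same model gave an F-test that the 8 differences were equal, and a contrast of 4 triple-negative lines against the other 4. That grouping is background knowledge and not a label. The contrast was set beside an exact permutation test over the 8 line values, for which 70 splits allow no two-sided p below 0.0286. Each line was also tested alone, on miRNAs with a mean of at least 10 CPM in its 6 libraries. The arm ratio, log2(5p + 1) minus log2(3p + 1), was tested on hairpins with both arms at a mean of at least 10 CPM. Values of each arm were first summed over the hairpin copies of a miRNA that are listed for every line. A hairpin in this test can therefore stand for several copies. Levels of the CTRL groups were compared by an F-test. Because the joined tables were probably scaled separately, differences between lines were tested only within each table, for each table alone and jointly. This departs from the planned single test, and SUM159PT, alone in its table, was left out.

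A set of 14 miRNA lists was fixed, and the 10 lists with at least 3 tested members went into camera (inter-gene correlation 0.01, and estimated as an alternative) and fry. The lists held reported ZSWIM8 or target-directed degradation substrates, members of the seed families of some of them, miRNAs degraded through viral RNAs, the let-7 family, and the miR-17-92 cluster with its paralogs. They also held epithelial, basal or mesenchymal, stromal, blood, and liver, muscle or neuron miRNAs, p53-responsive miRNAs, the hypoxia miRNA miR-210-3p, and the 14q32 and 19q13 clusters. The list of reported substrates came from background knowledge and was not chosen on these samples.

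The miRNAs named in the text follow a rule. It takes the 15 largest increases and 10 largest decreases called in the all-line comparison, all members of the reported list and of its family list, up to 5 called miRNAs per direction in each line, the 8 with the smallest adjusted p in the F-test, the other arm of each increase, and 2 to 4 abundant members of each list. Further miRNAs are said to be chosen after their values were seen. Groups, tests, lists, this rule and the alternatives below were fixed before the data were examined. The alternatives were pseudocounts of 0.5 and 5, no filter or a filter at 100 CPM, median-of-ratios or quantile rescaling within each line, no trend, array weights, the sgRNA number as a replicate block, 1 model for all 48 libraries, a log2 change of at least 0.5, lines as replicates, arms of at least 50 CPM, and leaving out each library or line.

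Whether the numbers pair CTRL and KD libraries was checked by correlating deviations from the group means. Every pair was correlated above 0.1 in T47D alone, at 0.24, 0.13 and 0.17 for numbers 1, 2 and 3. The pairing there comes from the data and not from the labels. All tests were first run on simulated data. With 408 simulated miRNAs, the all-line test recovered 85% of changes of 0.3 log2 and 100% of those of 0.6 log2, and 3.75% of its calls were unchanged miRNAs. The F-test recovered 85% of changes of 1 log2 present in 2 lines, and 19% of its calls were unchanged miRNAs, so it was liberal. The single-line tests recovered 25% to 50% of changes of 0.3 log2 and 57.9% to 90% of those of 0.6 log2. Coordinates come from GENCODE release 29 (GRCh38), in which 1803 of the miRNAs matched a gene. That build may differ from the authors'. Tables and figures used Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.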

Results

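MicroRNA levels were measured by small RNA sequencing in 8 breast cancer cell lines after CRISPR interference against ZSWIM8. ZSWIM8 is the substrate receptor of a cullin ubiquitin ligase that acts in target-directed miRNA degradation, in which pairing of a miRNA with a specialised target RNA leads to decay of its Argonaute protein and then of the miRNA. The knockdown of ZSWIM8 itself was not analysed here, because small RNA libraries do not measure mRNA. SUM159PT, BT-549, MDA-MB-231 and MDA-MB-436 are triple-negative lines, MCF-7 and T47D are estrogen receptor-positive lines, and SK-BR-3 and MDA-MB-361 are lines with HER2 amplification. Each line had 3 CTRL and 3 KD libraries, all with different sgRNAs. Estimated depth was 1.80 M to 6.02 M reads per library, with means of 3.24 M in the 24 CTRL and 3.5 M in the 24 KD libraries. From 232 to 330 miRNAs reached 10 CPM in a library. A single miRNA, miR-21-5p, took 54.4% to 60.1% of the CPM total in MCF-7.

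The first question was which miRNAs changed with ZSWIM8 knockdown across the lines. Apart from miR-3529-3p, which is described below with the hairpins, the largest increases were those of miR-7-5p, a brake on growth factor signalling, and miR-335-3p, the less studied arm of an imprinted hairpin. The log2 change of miR-7-5p was 1.34 (SE 0.107, adjusted p = 4.86e-13), and all 24 KD libraries lay above the CTRL mean of their line. Its mean over lines was 12.3 CPM in CTRL and 32 CPM in KD libraries. For miR-335-3p, the log2 change was 0.98 (SE 0.0488, adjusted p = 2.55e-19), with 23 of 24 KD libraries above the CTRL mean. Its mean was 334 CPM in CTRL and 820 CPM in KD libraries, and it was listed at 0 in all CTRL libraries of T47D. The decrease with the smallest adjusted p was that of miR-182-5p, an oncogenic miRNA of the miR-183 cluster. It fell by 0.29 (SE 0.0208, adjusted p = 3.28e-14), from 22216 to 18206 CPM, and was below the CTRL mean in all 24 KD libraries. These means run over lines whose tables were probably scaled separately, while the tests use differences within lines.

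Hairpin positions are given on GRCh38. MIR335 lies at chromosome 7, 130496111 to 130496204, in an intron of MEST. The 3 hairpins that yield miR-7-5p are MIR7-1 at chromosome 9, 83969748 to 83969857, within HNRNPK, MIR7-2 at chromosome 15, 88611825 to 88611934, outside annotated host genes, and MIR7-3 at chromosome 19, 4770670 to 4770779, in an intron of MIR7-3HG. MIR182 lies at chromosome 7, 129770383 to 129770492, outside annotated host genes. The table also lists miR-3529-3p, from MIR3529 at chromosome 15, 88611847 to 88611924, on the strand opposite MIR7-2. The full 78 bases of MIR3529 are complementary to MIR7-2, so reads of miR-3529-3p and miR-7-5p cannot be separated here if reads were counted without regard to strand. In that case the CPM levels given for miR-7-5p may hold only a part of its reads. The increase listed for miR-3529-3p was 1.00 (SE 0.103, adjusted p = 7.63e-10), with all 24 KD libraries above the CTRL mean.

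**Figure D1:**
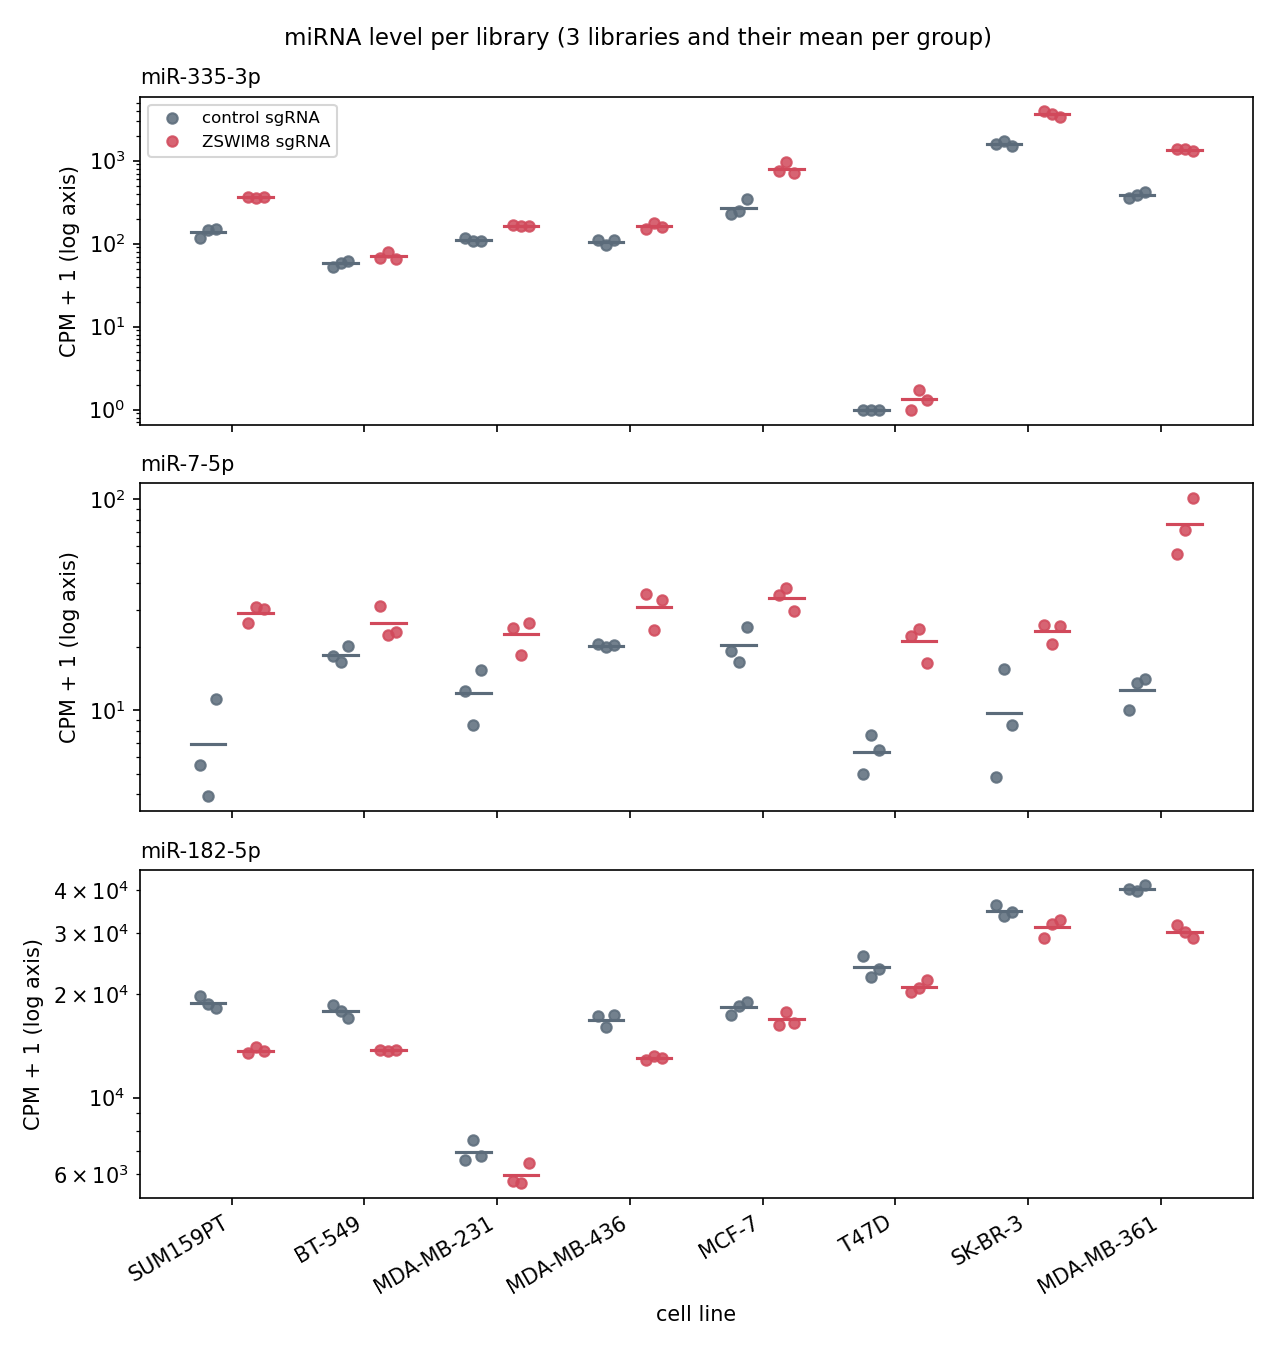
Level of miR-335-3p, miR-7-5p and miR-182-5p in each library (points, CPM + 1 on a log axis) by cell line, with the mean of 3 CTRL or 3 KD libraries as a bar. Values of miR-7-5p in all 24 KD libraries lie above, and those of miR-182-5p below, the CTRL mean of their line.

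Smaller increases were called for miR-125b-5p and miR-146b-5p, the latter a feedback inhibitor of NF-kB signalling. The log2 change was 0.62 (SE 0.161, adjusted p = 0.00801) for miR-125b-5p and 0.60 (SE 0.133, adjusted p = 0.00266) for miR-146b-5p, each with 21 of 24 KD libraries above the CTRL mean. The other named increases were miR-186-3p (0.51), miR-550a-3p (0.43), miR-331-3p (0.40), miR-550b-2-5p (0.38), miR-326 (0.38), miR-1307-5p (0.36), miR-106a-5p (0.35), miR-33b-5p (0.35), miR-205-5p (0.33) and miR-188-5p (0.32). Of these, miR-186-3p, miR-550a-3p and miR-326 had means under 5 CPM in both groups. MIR550A2 and MIR550B2 lie on opposite strands at chromosome 7, 32732981 to 32733077, so miR-550a-3p and miR-550b-2-5p are open to the same doubt about strand as miR-3529-3p. The epithelial miRNA miR-205-5p had means of 18463 ± 3227 (SD, n = 3) CPM in CTRL and 31166 ± 9124 (SD, n = 3) CPM in KD libraries of MDA-MB-361, a change not called in that line alone (adjusted p = 0.103). Decreases beside miR-182-5p were small. They were miR-100-5p (-0.27), miR-99b-5p (-0.22), miR-501-3p (-0.21), miR-340-3p (-0.20), miR-27b-5p (-0.18), miR-96-5p (-0.17), miR-3615 (-0.16), miR-130b-5p (-0.16) and miR-27a-5p (-0.13).

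In total, 55 of 408 tested miRNAs were called, 42 higher and 13 lower in KD libraries. Of these, 12 increases were positive and 4 decreases negative in all 8 lines. The split of calls depended on scaling: it was 31 higher and 24 lower after median-of-ratios rescaling and 27 of each after quantile normalization, with 25 increases and 12 decreases called under all 3 scalings. Leaving out CTRL 1 of every line gave 24 calls, leaving out CTRL 2 gave 32, leaving out CTRL 3 gave 78 (70 higher and 8 lower), and taking lines as replicates gave 23. The call for miR-125b-5p was lost without CTRL 2 (adjusted p = 0.0692), and its KD mean exceeded CTRL 1 in 4 of 8 lines. For miR-146b-5p the change was 0.95 against CTRL 1, 0.55 against CTRL 2 and 0.29 against CTRL 3, which the KD mean exceeded in 4 of 8 lines. Against CTRL 3, the change was also small for miR-1307-5p (0.02), miR-33b-5p (0.05), miR-331-3p (0.09), miR-106a-5p (0.12) and miR-188-5p (0.14), so these increases rest mainly on CTRL 1 and CTRL 2. The calls for miR-106a-5p and miR-33b-5p were lost after quantile normalization (adjusted p = 0.0568 and 0.0542), and the call for miR-106a-5p also after median-of-ratios rescaling (0.0529). That call was lost in 43 of 70 alternatives, 31 of them single libraries left out, so it was not stable. Among the decreases, leaving out 1 of the 48 libraries ended the call for miR-100-5p in 17 cases, miR-96-5p in 21, miR-340-3p in 27 and miR-27a-5p in 27. Calls of the increases and decreases named above, except those of miR-335-3p, miR-7-5p, miR-3529-3p, miR-146b-5p and miR-182-5p, were each lost in at least 1 of these settings: without CTRL 1 or CTRL 2 of every line, without 1 whole line, or with lines as replicates.

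The next question was whether miRNAs reported as substrates of this pathway responded. Of 8 tested members of that list, 3 rose: miR-7-5p, miR-335-3p and miR-29b-3p, a repressor of collagen genes, at 0.18 (adjusted p = 0.0171). The other members were not called, at 0.08 for miR-30b-5p, 0.05 for miR-30c-5p, -0.06 for miR-221-3p, -0.06 for miR-222-3p and -0.12 for miR-424-5p. Levels of miR-503-5p were outside the all-line test. Adjusted over the list alone, 5 members were higher and 1 was lower. The list was called in camera (adjusted p = 0.0112), but not with an estimated correlation (adjusted p = 0.248 with an estimated correlation) or with a filter at 100 CPM (adjusted p = 0.469). Its median change was 0.07 and its mean 0.30. In single lines the list was called in SUM159PT (adjusted p = 0.0134, and 0.399 with an estimated correlation) and MDA-MB-361 (adjusted p = 0.0183, and 0.339 with an estimated correlation). Without CTRL 1 or without CTRL 2 of every line the call for miR-29b-3p was lost (adjusted p = 0.0507 and 0.0509). It was also lost with lines as replicates (adjusted p = 0.255), without SUM159PT (0.308) and without BT-549 (0.158), and its change was positive in 5 of 8 lines.

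Relatives of these miRNAs that share their seed showed little change. Of 10 tested family members, miR-30d-5p rose (0.10, adjusted p = 0.00955) and 9 were not called. The count was the same adjusted over the list alone, and camera gave an adjusted p of 0.465. The call for miR-30d-5p was lost after median-of-ratios and quantile rescaling (adjusted p = 0.0780 and 0.275). The uncalled members were miR-195-5p (0.11), miR-15a-5p (0.08), miR-16-5p (0.07), miR-497-5p (0.07), miR-29c-3p (0.06), miR-30e-5p (0.02), miR-30a-5p (-0.0018), miR-29a-3p (-0.0019) and miR-15b-5p (-0.01).

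Other fixed lists gave no camera call. Among 4 miRNAs that viral RNAs degrade, miR-17-5p (0.16) and miR-20a-5p (0.19) rose and miR-27b-3p fell by 0.11, the same 3 adjusted over the list alone (camera adjusted p = 0.918). The calls for miR-17-5p and miR-20a-5p were lost after quantile normalization (adjusted p = 0.111 and 0.139). Of 12 tested members of the miR-17-92 cluster and its paralogs, 3 rose, both over all miRNAs and adjusted over the list alone (camera adjusted p = 0.437). None of 9 let-7 members was called in limma, by either adjustment (camera adjusted p = 0.437). Among let-7 members, let-7a-5p changed by 0.04 and let-7f-5p by 0.02. Of 8 epithelial miRNAs, miR-205-5p alone rose, also adjusted over the list alone (camera adjusted p = 0.918), while miR-200c-3p changed by 0.11 and miR-375 by 0.08. The call for miR-205-5p was lost without T47D (adjusted p = 0.0986), without MDA-MB-361 (0.0557), without CTRL 1 of every line (0.0507) and with lines as replicates (0.060). Of 8 basal or mesenchymal miRNAs, miR-125b-5p and miR-146a-5p (0.32) rose and miR-100-5p fell, with the same count adjusted over the list alone. That list had a median of -0.05, a mean of 0.06 and a downward camera test (adjusted p = 0.529).

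Among 5 p53-responsive miRNAs, miR-192-5p rose (0.09), a call lost after both rescalings (adjusted p = 0.185 and 0.877). The p53 effector miR-34a-5p changed by 0.10 and was not called. Adjusted over the list alone, 2 of the 5 were higher (camera adjusted p = 0.457). In fry, which asks whether the members of a list changed without comparing them with other miRNAs, the p53 list was called upward (adjusted p = 0.00725), as was the reported list (adjusted p = 5.45e-09). The other 8 lists were not called in fry (adjusted p of at least 0.0846). Fry was examined on the deposited scale only, where the median change of all tested miRNAs was 0.03, and not after rescaling. The hypoxia-induced miR-210-3p rose by 0.14 (adjusted p = 0.00402), a call lost after quantile normalization (adjusted p = 0.103). Neither the 4 stromal miRNAs nor the 4 of the 14q32 cluster held a call over all miRNAs (camera adjusted p = 0.292 and 0.139). Adjusted over the list alone, these counts were 0 and 1, the latter miR-127-3p at -0.32. Of 2 tested blood miRNAs none was called over all miRNAs and 1, miR-142-5p at 0.36, adjusted over the list alone. The liver, muscle or neuron list and the 19q13 list had 0 members above the filter.

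Target-directed degradation acts on the miRNA loaded in Argonaute, so the 2 arms of a hairpin were compared. The 3p arm of miR-335 rose while its 5p arm changed by -0.01 (95% CI -0.10 to 0.08), and the difference of 5p minus 3p was -0.99 (SE 0.0537, adjusted p = 5.07e-18). For miR-7, the 5p arm rose while miR-7-1-3p changed by -0.06 (95% CI -0.28 to 0.17), a difference of 1.40 (SE 0.129, adjusted p = 2.80e-11). That 3p arm belongs to MIR7-1, while miR-7-5p is also made from MIR7-2 and MIR7-3. A change in the output of those hairpins is not told apart here. For miR-125b, made from 2 hairpins, the 5p arm rose while miR-125b-1-3p changed by -0.05. The 3p arm of its second hairpin, miR-125b-2-3p, changed by 0.15 (95% CI -0.01 to 0.31) and was not called. With the 3p arms summed, the difference of 5p minus 3p was 0.67 (SE 0.181, adjusted p = 0.0111). For miR-181a the 5p arm rose by 0.13 and miR-181a-3p changed by -0.02. The tested difference, with the 3p arms of its hairpin copies summed, was 0.13 (adjusted p = 0.00771). Among the other arms of named increases, miR-186-5p rose by 0.08, while miR-205-3p (0.13), miR-1307-3p (0.06), miR-550a-5p (-0.0032) and miR-331-5p (-0.09) were not called. Of 78 hairpins, 10 were called, 4 with a higher and 6 with a lower ratio of 5p to 3p. The others were miR-340 (0.41), miR-454 (-0.26), miR-99b (-0.24), miR-148b (-0.23), miR-210 (-0.22) and miR-151a (-0.11). Quantile normalization ended the calls for miR-181a, miR-99b and miR-151a (adjusted p = 0.0580, 0.108 and 0.0957). The call for miR-99b was also lost in 12 of 48 cases of leaving out 1 library.

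**Figure D2:**
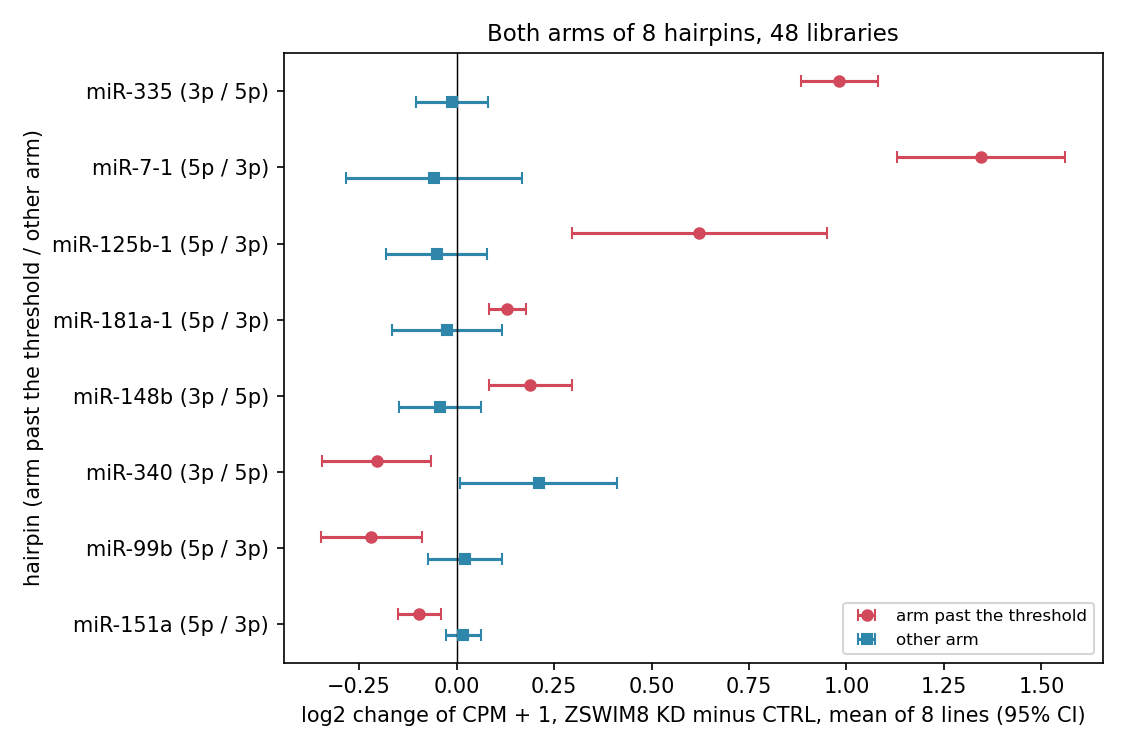
Log2 change of both arms of 8 hairpins, as the mean of 8 within-line differences with 95% confidence intervals, for the called arm (circles) and the other arm (squares). The 3p arm of miR-335 lies at 0.98 and its 5p arm at -0.01.

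Each line was then tested alone. In SUM159PT, miR-335-3p rose from 137 ± 18.9 to 360.5 ± 7.48 CPM (SD, n = 3, log2 change 1.40, adjusted p = 0.000544). The level of miR-7-5p rose from 5.90 ± 3.89 to 28.0 ± 2.64 CPM (2.22, adjusted p = 0.0262), and miR-29b-3p from 134 ± 12 to 226 ± 9.60 CPM (0.75, adjusted p = 0.00435). Increases were also called for miR-3529-3p (1.77) and miR-181a-5p (0.27), while miR-182-5p went from 18851 ± 803 to 13689 ± 285 CPM (-0.46, adjusted p = 0.00435). Of 322 miRNAs, 6 were called. Without CTRL 1, 2 or 3 there were 5, 3 and 57 calls in SUM159PT, and without KD 1, 2 or 3 there were 3, 2 and 3. Those for miR-335-3p and miR-182-5p held each time, that for miR-29b-3p failed without KD 2, and those for miR-7-5p, miR-3529-3p and miR-181a-5p held only without CTRL 3. Rescaling ended the call for miR-181a-5p (adjusted p = 0.242 and 0.422).

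BT-549 had 3 calls among 310 miRNAs. The level of miR-29b-3p rose from 106 ± 4.57 to 158 ± 6.09 CPM (SD, n = 3, log2 change 0.57, adjusted p = 0.0144). Both miR-182-5p (-0.38, adjusted p = 0.0144) and miR-130b-5p (-0.45, adjusted p = 0.0452) fell, the former from 17816 ± 773 to 13698 ± 49.6 CPM. The calls split 1 higher and 1 lower after median-of-ratios rescaling and 1 and 0 after quantile normalization. Both ended the call for miR-130b-5p (adjusted p = 0.0622 and 0.0953), and quantile normalization that for miR-182-5p (0.0525). No miRNA (0) was called when CTRL 1, CTRL 2, KD 2 or KD 3 was left out, while leaving out CTRL 3 or KD 1 gave 3 and 4, with 50 miRNAs at an unadjusted limma p under 0.05 over all 6 libraries.

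In MDA-MB-231, miR-335-3p was the 1 miRNA called of 269, with an increase from 109 ± 5.32 to 164 ± 4.12 CPM (SD, n = 3, log2 change 0.59, adjusted p = 0.0327). The level of miR-7-5p was 11.1 ± 3.5 CPM in CTRL and 21.9 ± 4.03 CPM in KD libraries, and it was not called. Rescaling by median of ratios or quantiles left 0 calls (adjusted p of miR-335-3p = 0.0688 and 0.307), with 26 miRNAs at an unadjusted limma p under 0.05 on the deposited scale. The count was also 0 without CTRL 1 or any KD library, and leaving out CTRL 2 or 3 gave 3 and 7.

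MDA-MB-436 had 4 calls among 287 miRNAs. The NF-kB-induced miR-146a-5p rose from 202 ± 64.9 to 417 ± 102 CPM (SD, n = 3, log2 change 1.07, adjusted p = 0.0363), and miR-335-3p from 105 ± 8.44 to 162 ± 14.6 CPM (0.62, adjusted p = 0.0363). Both miR-182-5p (-0.37, adjusted p = 0.0126) and miR-100-5p (-0.58, adjusted p = 0.0474) fell, the former from 16835 ± 758 to 13027 ± 172 CPM. Median-of-ratios rescaling gave 1 higher and 3 lower and quantile normalization 2 and 0, and both ended the call for miR-335-3p (adjusted p = 0.0591 and 0.0920). Quantile normalization ended the other 3 calls as well (adjusted p = 0.239 for miR-146a-5p, 0.296 for miR-100-5p and 0.239 for miR-182-5p), so its 2 calls were other miRNAs. Without CTRL 1, 2 or 3 there were 2, 1 and 7 calls, and without KD 1, 2 or 3 there were 0, 0 and 2, with 28 miRNAs at an unadjusted limma p under 0.05 over all 6 libraries.

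MCF-7 had 15 calls among 244 miRNAs, all higher, while the median change of all miRNAs in this line was 0.15. The level of miR-335-3p rose from 271 ± 63.1 to 803 ± 131 CPM (SD, n = 3, log2 change 1.58, adjusted p = 0.000141), or 1.43 above the median change. Next by size were miR-33b-5p, encoded in SREBF1 (0.96), miR-3194-5p (0.88), miR-940 (0.87) and miR-1307-5p (0.86), which were 0.81, 0.73, 0.72 and 0.72 above the median change. An increase of miR-7-5p was also called (0.76, or 0.61 above the median change). Its call was kept after median-of-ratios rescaling (adjusted p = 0.0303) and lost after quantile normalization (0.0554). The abundant miR-21-5p took 581715 ± 27652 CPM in CTRL and 552266 ± 6835 CPM in KD libraries. Calls split 11 higher and 3 lower after median-of-ratios rescaling and 3 and 3 after quantile normalization. The 3 miRNAs that kept their call under both were miR-335-3p, let-7c-5p and miR-193a-3p, the last 2 named after their values were seen. Leaving out CTRL 1, 2 or 3 gave 8, 1 and 119 calls, and leaving out any KD library gave 1, that of miR-335-3p.

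In T47D, where miR-335-3p was at most 0.7 CPM, miR-7-5p rose from 5.37 ± 1.31 to 20.2 ± 4.01 CPM (SD, n = 3, log2 change 1.74, adjusted p = 0.0208). Increases of miR-331-3p (0.95, adjusted p = 0.0237) and miR-1269a (0.83, adjusted p = 0.0237) were called, each from 8.47 CPM in CTRL libraries. The smooth muscle-associated miR-143-3p fell by 0.67 (adjusted p = 0.0361), from 32.4 ± 1.64 to 20 ± 1.36 CPM, and miR-27b-3p fell by 0.34 (adjusted p = 0.0237). Of 247 miRNAs, 5 were called. With the sgRNA number as a block the calls for miR-1269a and miR-143-3p were lost (adjusted p = 0.0509 and 0.0679). Calls split 4 higher and 3 lower after median-of-ratios rescaling and 4 and 1 after quantile normalization, which ended the calls for miR-331-3p (adjusted p = 0.0521) and miR-27b-3p (0.321). Leaving out CTRL 1, 2 or 3 gave 9, 1 and 0 calls, and leaving out KD 1, 2 or 3 gave 1, 0 and 1, with 42 miRNAs at an unadjusted limma p under 0.05 over all 6 libraries.

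SK-BR-3 had the highest level of miR-335-3p of the 8 lines, and this was its 1 call among 242 miRNAs. The level rose from 1608 ± 104 to 3648 ± 293 CPM (SD, n = 3, log2 change 1.18, adjusted p = 0.000118), a call kept without each library in turn. The level of miR-7-5p was 8.67 ± 5.54 CPM in CTRL and 22.7 ± 2.57 CPM in KD libraries, and it was not called. Without CTRL 1 or CTRL 2 there were 2 calls.

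In MDA-MB-361, miR-7-5p rose from 11.5 ± 2.19 to 75 ± 23.4 CPM (SD, n = 3, log2 change 2.58, adjusted p = 0.000339) and miR-335-3p from 383 ± 30.9 to 1349 ± 51.5 CPM (1.82, adjusted p = 2.60e-06). Both calls held without each library in turn. Also called were miR-3529-3p (1.69, adjusted p = 0.00700) and miR-182-5p, which went from 40368 ± 873 to 30287 ± 1314 CPM (-0.42, adjusted p = 0.00584). Of 301 miRNAs, 4 were called, and quantile normalization gave 3 higher and 2 lower. Without CTRL 2, KD 1 or KD 2 there were 8, 11 and 2 calls, and without KD 2 those for miR-3529-3p and miR-182-5p were lost.

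Whether the response differed between lines was tested directly. For miR-335-3p, the change ran from 0.29 in BT-549 to 1.82 in MDA-MB-361 (F-test adjusted p = 1.14e-07), and for miR-7-5p from 0.48 in BT-549 to 2.58 in MDA-MB-361 (adjusted p = 0.00506). The range for miR-182-5p was -0.46 in SUM159PT to -0.11 in MCF-7 (adjusted p = 0.0248), a call lost after both rescalings (adjusted p = 0.189 and 0.0661). Both directions occurred for miR-744-5p, from -0.18 in BT-549 to 0.51 in SK-BR-3 (adjusted p = 0.00506), and for miR-320a, from -0.27 in MDA-MB-231 to 0.39 in T47D (adjusted p = 0.0248). The same was true of miR-1305, from -0.53 in MDA-MB-436 to 1.31 in T47D, where its KD mean was 2.57 CPM (adjusted p = 0.00641). For miR-105-5p the range was -1.34 in MDA-MB-436, with a CTRL mean of 2.13 CPM, to 0.27 in T47D (adjusted p = 0.0248). For miR-210-5p it was -0.76 in T47D to 0.24 in MDA-MB-231 (adjusted p = 0.0369). These 8 of 408 miRNAs were called. Without CTRL 3 of MCF-7, 39 were called, and without CTRL 1 of T47D, 13. Quantile normalization ended the calls for miR-320a and miR-210-5p (adjusted p = 0.155 and 0.0661), and that for miR-210-5p was also lost in 17 of 48 cases of leaving out 1 library.

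**Figure D3:**
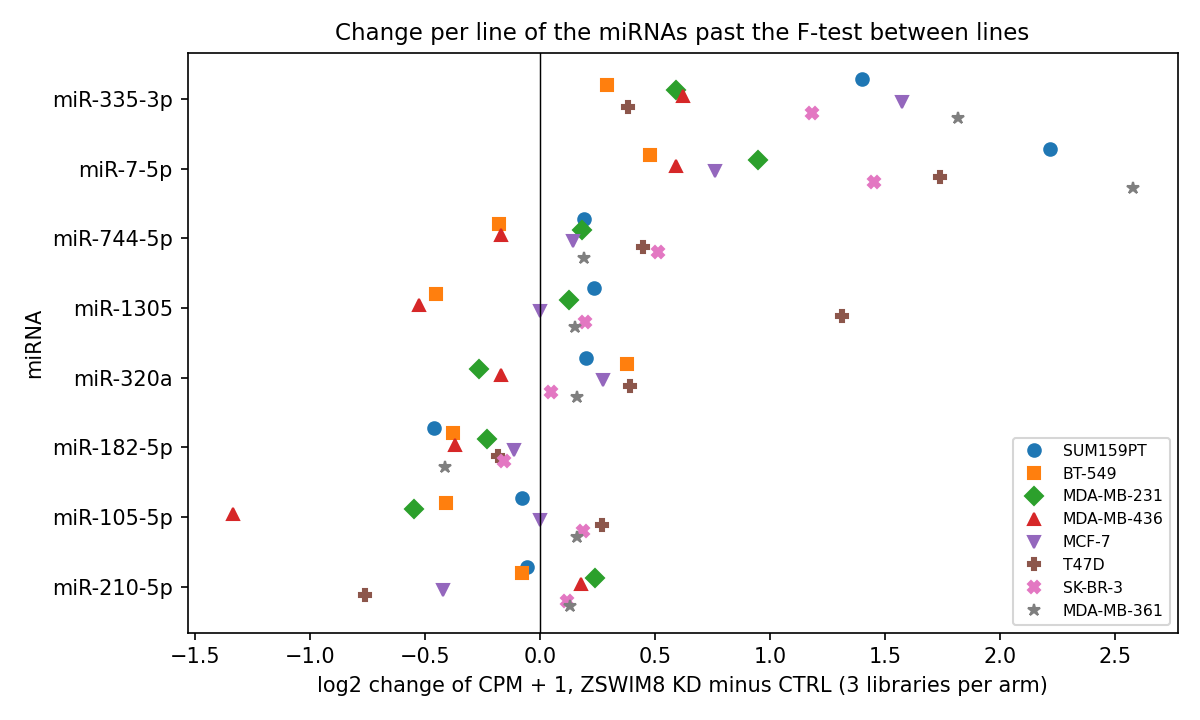
Log2 change of KD against CTRL libraries in each of 8 lines (symbols, 3 libraries per arm) for the 8 miRNAs called in the F-test between lines. The change of miR-335-3p ranges from 0.29 to 1.82 and that of miR-7-5p from 0.48 to 2.58.

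The 4 triple-negative lines were set against the other 4. The mean change of miR-335-3p was 0.72 in triple-negative and 1.24 in the other lines, a difference of -0.51 (SE 0.0977, adjusted p = 0.00237). Differences were also called for miR-744-5p (-0.32, adjusted p = 0.00798), miR-105-5p (-0.75, adjusted p = 0.0108) and miR-21-5p (0.14, adjusted p = 0.0235). Of 408 miRNAs, 4 were called. With the line as the unit, the exact permutation p was 0.286 for miR-335-3p, 0.114 for miR-744-5p and 0.0286 for miR-105-5p and miR-21-5p. After adjustment over 47 exact tests these were 0.591, 0.591, 0.448 and 0.448. With 4 against 4 lines and a smallest possible p of 0.0286, this test had almost no power to call a miRNA, so it leaves the question open for lines as units. The value for miR-335-3p includes T47D, where that miRNA was at most 0.7 CPM. Calls split 0 higher and 3 lower after median-of-ratios rescaling and 3 and 4 after quantile normalization, and the call for miR-21-5p was lost in both (adjusted p = 0.160 and 0.177).

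Levels without knockdown differed widely between the lines. The metastasis-associated miR-31-5p had 3433 ± 155 CPM in BT-549 and 1471 ± 56.6 CPM in MDA-MB-436 (SD, n = 3) and was listed at 0 in the CTRL libraries of MDA-MB-231. In the table of SK-BR-3 and T47D it had 416 ± 39.0 and 0.267 ± 0.462 CPM. Within the third table, miR-130a-3p had 279.5 ± 25.5 CPM in MDA-MB-361 and was listed at 0 in MCF-7. Within a table, 359 of 408 miRNAs differed between BT-549, MDA-MB-231 and MDA-MB-436, 327 between MCF-7 and MDA-MB-361, and 293 between T47D and SK-BR-3. A joint F-test of these within-table differences called 402, and it left out SUM159PT, which is alone in its table. On simulated data, 12.9% of the calls of this F-test were unchanged miRNAs, so it was liberal.

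Markers of cell types were compared in CTRL libraries. The summed epithelial miRNAs reached 62739 ± 3092 CPM in MDA-MB-361 and 6754 ± 658 CPM in MCF-7 (SD, n = 3). They were at 50.1 ± 5.94 CPM in MDA-MB-436 and 10.4 ± 3.35 CPM in BT-549. The summed basal or mesenchymal miRNAs were at 114154 ± 16197 CPM in SUM159PT and 420.5 ± 57.8 CPM in MDA-MB-361. Across these tables the levels were probably scaled separately. Stromal miRNAs were highest in SUM159PT and BT-549, where miR-199a-3p had 1841 ± 55.1 and 775 ± 70.6 CPM. The summed blood miRNAs were at 1378 ± 668 CPM in BT-549, 1082 ± 28.6 CPM in MDA-MB-231 and at most 163 ± 10.7 CPM elsewhere. Most of the BT-549 sum was miR-486-5p, at 1374 ± 668 CPM. In contrast, miR-142-5p had 678 ± 35.9 CPM in MDA-MB-231 and at most 7.90 ± 1.10 CPM in the other lines, and the erythroid miR-451a was under 2 CPM on average in each line. The sum of the liver, muscle or neuron list was at most 8.30 ± 3.46 CPM, in MDA-MB-436, and that of the 19q13 list at most 12.4 ± 0.493 CPM, in MCF-7.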

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

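The tests of explanations for miR-3529-3p, for CTRL 3 of SUM159PT and MCF-7 and for miR-182-5p were chosen after the results were seen. The change with knockdown differed between lines for 8 miRNAs, with adjusted p-values of the F-test of 1.14e-07 for miR-335-3p, 0.00506 for miR-7-5p, 0.00506 for miR-744-5p and 0.00641 for miR-1305. They were 0.0248 for miR-320a, miR-182-5p and miR-105-5p, and 0.0369 for miR-210-5p. Values of miR-1305 in T47D and of miR-105-5p in MDA-MB-436 were near the floor of a few CPM. Redrawing the CTRL and KD labels within lines gave as many calls in 2 of 100 draws, the real labels included. The real labels gave 8 calls and the highest other draw gave 9. Redrawn labels remove every change with knockdown, also one that is equal in all lines. The draws therefore cannot tell whether the changes differed between lines. Individual calls are also unsure, since 19% of calls on simulated data were unchanged miRNAs.

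Between the triple-negative and the other lines, the change differed by -0.51 for miR-335-3p, -0.32 for miR-744-5p, -0.75 for miR-105-5p and 0.14 for miR-21-5p. Of the 35 splits of the lines into 4 and 4, 5 gave at least the 4 real calls. The highest other split gave 11, with SUM159PT, T47D, SK-BR-3 and MDA-MB-361 against the rest, so chance is not excluded for this grouping.

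For the all-line comparison, 1 of 100 draws, the real one, gave as many as 55 calls, and the highest other gave 3. The arm ratio gave 10 calls in 1 of 100 draws and at most 2 in the others. Redrawing CTRL libraries among lines of the same table gave 402 calls in 1 of 100 draws and at most 306 in the others. Chance is excluded for these 3 counts if the libraries are independent. The sgRNA numbers recur in every line, and redrawing labels within lines does not cover an effect of 1 guide shared by several lines. Chance is not excluded for the count of called lists, since 32 of 100 draws called at least 1 list and the highest other called 2.

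In single lines, 3 against 3 libraries allow 10 splits, too few for a share under 0.05. The real split, 1 of 10, gave 6 calls in SUM159PT, 3 in BT-549, 1 in MDA-MB-231, 4 in MDA-MB-436, 15 in MCF-7, 5 in T47D, 1 in SK-BR-3 and 4 in MDA-MB-361. The highest other split gave 2 in SUM159PT, 1 in MDA-MB-436 and 0 in the other lines. In T47D, where every same-number pair was correlated, the 4 splits that part each of these pairs include the real one. The highest other of them gave 0, but the pairing itself is not established.

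The increase listed for miR-3529-3p may come in part from miR-7-5p reads counted on the opposite strand. Its mean over all libraries was 57.6 CPM, against 22.1 CPM for miR-7-5p. If miR-7-5p reads were counted there, the listed levels of miR-7-5p hold only a part of its reads. In 3 of the 4 other pairs of arms on opposite strands with both arms listed for every line at a mean of at least 10 CPM, the log2 ratio was steadier over libraries than in 95% of 10000 random pairs (SD 0.0360, 0.306 and 0.0569, against a limit of 0.789). The exception was miR-3074-5p with miR-24-3p (0.859), and the pair of miR-7-5p had 0.373. Pairs below that level, such as miR-550a-3p with miR-550b-2-5p, were not tested. A fixed split between the strands as the whole value is excluded, since miR-3529-3p changed by -0.34 relative to miR-7-5p (95% CI -0.49 to -0.20). Whether MIR3529 is itself transcribed and raised cannot be told apart, because its other arm, miR-3529-5p, was at most 0.3 CPM in the 18 libraries that list it, near the floor.

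CTRL 3 of SUM159PT and of MCF-7 lay nearer to the KD libraries than to the other CTRL libraries, with root mean square distances of 0.277 against 0.394 and 0.238 against 0.369 (log2). A KD library in its place is excluded: on miR-335-3p these libraries lay 0.0936 and 0.189 of the way from the other CTRL libraries to the KD mean. KD RNA mixed in is excluded as the whole cause, since the other miRNAs called without the library lay at a median of 0.984 of the way in SUM159PT (quartiles 0.498 to 1.45) and 0.953 in MCF-7 (quartiles 0.634 to 1.21). The sequence of the third control sgRNA cannot be told apart from other causes, since CTRL 3 lay nearer to the KD mean in 2 of 6 other lines, against 3 of these 6 for CTRL 1 and 2 for CTRL 2. In MCF-7, miR-21-5p took 60.1% and 59.4% of CTRL 1 and CTRL 2, 55.0% of CTRL 3 and 54.4% to 55.7% of the KD libraries. Without CTRL 3 the calls rose from 6 to 57 in SUM159PT and from 15 to 119 in MCF-7 (112 higher and 7 lower), so most of those calls rest on CTRL 1 and CTRL 2 alone. A shift in the share of miR-21-5p could move many other miRNAs of MCF-7 together. Rescaling, which removes a shared shift, changed the 15 higher calls of this line to 11 higher and 3 lower (median of ratios) or 3 and 3 (quantile). The part of miR-21-5p in such a shift was not tested.

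The decrease of miR-182-5p in all 8 lines was small. Its size was called different between lines in the F-test, but that call was lost after both rescalings, so a difference is not established. Scaling of the libraries as the cause of the decrease is excluded, since the decrease remained at -0.26 after quantile normalization and -0.33 after median-of-ratios rescaling. Less transcription of the whole cluster is excluded as the whole cause, since miR-182-5p changed by -0.29 relative to miR-183-5p (95% CI -0.35 to -0.23). Relative to miR-96-5p it changed by -0.12 (95% CI -0.25 to 0.01), so a change shared by these 2 miRNAs stays open. A specific effect of ZSWIM8 loss on mature miR-182-5p is a hypothesis that was not tested here.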

How the results depend on the processing

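Leaving out CTRL 1, 2 or 3 in every line, and reading blank cells as 0, were tests chosen after the results were seen; the others were planned. A count-based test was not run, because whole reads could not be recovered, and the trend does not apply to the arm ratio. Of 5262 results for single miRNAs, hairpins and lists under the alternatives, 4753 were the same, 489 weaker, 20 stronger and 0 reversed. Leaving out 1 library gave 3675 of the 5262, and a result that stayed uncalled was taken as the same. Weaker results were 15 of 41 without CTRL 1 of every line, 13 of 41 without CTRL 2 and 14 of 41 with lines as replicates. They were 24 of 109 after quantile normalization and 0 of 110 with a pseudocount of 0.5. The all-line calls of miR-335-3p, miR-7-5p, miR-3529-3p and miR-146b-5p were kept throughout, although the size of the miR-146b-5p change differed between the control sgRNAs, and that of miR-182-5p was lost only when a log2 change of at least 0.5 was required. At the lowest depth of 1.80 M reads, 1 CPM is fewer than 2 reads, so changes of miRNAs near that level were not resolved. The cause of the moved values below was not tested.

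All-line calls went from 55 to 6 with a log2 change of at least 0.5, 23 with lines as replicates, 24 without CTRL number 1 and 32 without CTRL number 2. The F-test between lines gave 13 calls with a pseudocount of 5, 4 with no filter, 76 with array weights and 4 with a replicate block, against 8. The triple-negative contrast gave 7 after quantile normalization, 8 with array weights and 2 with a replicate block, against 4. The arm ratio gave 16 with a pseudocount of 5 and 6 with a filter at 100 CPM, against 10. Lists called were 2 with a pseudocount of 5, 0 with a filter at 100 CPM and 0 with an estimated correlation, against 1. CTRL groups differed in 607 miRNAs with no filter and 217 with a filter at 100 CPM, against 402, as the number tested changed.

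In SUM159PT, calls went from 6 to 2 without a trend. In BT-549 they went from 3 to 0 with no filter, 1 after quantile normalization, 0 with a replicate block and 1 with a log2 change of at least 0.5. In MDA-MB-231 they went from 1 to 3 with no filter, 0 after either rescaling, 0 without a trend, 0 with a replicate block and 2 in 1 model of 48 libraries. In MDA-MB-436 they went from 4 to 10 with no filter, 2 with a filter at 100 CPM, 2 after quantile normalization, 0 without a trend and 2 with a replicate block. In MCF-7 they went from 15 to 1 with no filter, 4 with a filter at 100 CPM, 6 after quantile normalization, 6 without a trend, 126 with array weights and 7 in 1 model. In T47D they went from 5 to 0 with no filter, 0 with a filter at 100 CPM, 11 with array weights and 24 in 1 model. In SK-BR-3 they went from 1 to 4 with no filter, 2 without a trend and 4 in 1 model. In MDA-MB-361 they went from 4 to 13 with no filter, 2 with a filter at 100 CPM, 36 with array weights and 7 in 1 model.

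Leaving out 1 library gave 44 to 68 all-line calls, 6 to 39 in the F-test, 3 to 6 in the triple-negative contrast, 9 to 15 arm ratios, 1 to 1 lists and 398 to 402 miRNAs between CTRL groups. In single lines it gave 2 to 57 calls in SUM159PT, 0 to 4 in BT-549, 0 to 7 in MDA-MB-231, 0 to 7 in MDA-MB-436, 1 to 119 in MCF-7, 0 to 9 in T47D, 1 to 2 in SK-BR-3 and 2 to 11 in MDA-MB-361. Limma gave 43, 50, 26, 28, 49, 42, 29 and 54 miRNAs at an unadjusted p under 0.05 in these lines, in that order. Outside T47D no line had all same-number pairs correlated above 0.1, although their mean was 0.195 in SUM159PT. The block values are therefore a hint from the data only. With the number as a block, the F-test calls of miR-744-5p (adjusted p = 0.118), miR-320a (0.0685), miR-182-5p (0.139) and miR-210-5p (0.139) were lost, and so were the all-line calls of miR-100-5p, miR-96-5p and miR-27a-5p and the arm-ratio calls of miR-99b and miR-151a.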

Other observations

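The comparison of miR-125b-5p with miR-100-5p is a test chosen after the results were seen. MIR125B1 lies in an intron of MIR100HG, the host transcript of miR-100, and the 2 miRNAs had changes of opposite sign. The change of miR-125b-5p minus that of miR-100-5p was 0.89 (95% CI 0.50 to 1.27). Both changes were known when the pair was chosen, so this interval cannot serve as independent support. The change of miR-125b-5p also differed between the control sgRNAs, at 0.30 against CTRL 1, 0.77 against CTRL 2 and 0.80 against CTRL 3. The decrease of miR-100-5p alone was not stable, as its call was lost in 28 of 71 alternatives. The second hairpin of miR-125b-5p, MIR125B2, lies on chromosome 21 in MIR99AHG, and its share of the miRNA was not measured.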
